A study of Mus musculus with 26 samples.

How the data were processed

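Each fraction of EML cells was sampled 3 or 4 times, and total RNA was extracted with TRIzol, checked on a BioAnalyzer, amplified with spike-in RNA and labelled with Cy3, per the labels' protocols. The cells grew in medium with horse serum and stem cell factor, per the labels. Per the labels, the cells were sorted on Sca1, CD34 and cKit, and Ediff samples came from cells negative for CD34 and cKit. The dose and time of Epo, the cutoffs of the gates and whether CD34- CD103- Epo cells were sorted after Epo are not given in the sources used here. Samples were placed in 8 groups from their titles, and the titles also separate the EryCP samples measured again from the first ones. The slide numbers divided the 26 arrays into 3 sets of 9, 6 and 11, on 3, 2 and 3 slides, and each set was scanned on 1 day with 1 scan time per slide, so scan date could not be tested apart from slide. EryCP of the first set and EryCP repeat of the second lie on different slides, and batch and group cannot be told apart between them, so that levels were tested only within a set.

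Per the file headers, each array was read by Agilent Feature Extraction, in version 10.1.1.1 for the first and second sets and 10.7.1.1 for the third. The deposited scanner files hold spot intensity values on a linear scale: the background-subtracted processed signal, the median signal, the median local background and marks for spots that are well above background, uneven or outlying. Per the file headers and their values, 0 spots were saturated. The deposited series table holds log2 values whose scale and centring are not stated. Set against the scanner values of the same arrays, its columns followed the log2 median signal in the first and second sets (r of at least 0.9946 and 0.997) and the log2 processed signal in the third (r of at least 0.9998). Its column medians were 7.18 to 7.21, 7.09 to 7.19 and 7.28 to 7.29, so that the centring step itself stays unknown.

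Probes were named through their accession in a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of 41174 probes on 43379 spots, with 1639 control spots left out, 27071 matched a symbol, 26690 through the newer and 381 through the older of the array's designs, and 14103 were unnamed here. The designs gave different symbols for 10 probes. The named probes covered 18378 symbols, and unnamed probes were counted 1 by 1 as genes, so that 16716 of the 26191 genes of the first set, 15844 of 24463 in the second and 16796 of 27075 in the third had a symbol. Hbb-b1, which was among the genes chosen in advance, was not matched to a probe here, and 344 of the 357 genes on the lists were.

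The log2 processed signal of each array was centred on its 75th percentile over non-control probes. Spots marked as uneven or outlying, 48 to 446 per array, were left out and spots of a probe were averaged. A probe counted as well above background on an array when at least 0.5 of its spots were, and was kept when this held on every array of at least 1 group of the set, with at least 2 measured arrays per group. Each gene was represented by its probe with the highest mean over the set. Where a gene had several probes, some but not all were often called: of 4243 such genes with a called probe in Ediff against EryCP repeat all probes were called the same way for 2051, some for 2055, and probes were called in both directions for 199, part of which also count among the 2055, against 0 or 1 in the other comparisons. Groups of a set were fitted together with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with the data.table package (version 1.17.8), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 per comparison. The difference between the Epo responses was a contrast of the group means of 13 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

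Groups of 3 or 4 arrays limit the precision. The median standard error of a log2 difference was 0.26 in the first set, 0.15 for Ediff against EryCP repeat, 0.13 for CD34- CD103- against CD34+ CD103- and 0.15 for CD34- CD103- Epo against CD34- CD103-. The same steps were run on data simulated with the real means and spreads, with changes of log2 0.5, 1 and 2. These were set in 67, 67 and 66 genes, fewer than were called in the data. Of the changed genes 0%, 17.9% to 20.9% and 47% to 65.2% were recovered in the first set. Ediff against EryCP repeat gave 4.48%, 41.8% and 78.8%, and CD34- CD103- against CD34+ CD103- 26.9%, 79.1% and 95.5%. The Epo comparison of that set gave 17.9%, 65.7% and 92.4%, and the difference of the Epo responses 2.99%, 35.8% and 78.8%. These shares do not give the sensitivity of the real comparisons. Median estimates lay within 0.07 of the simulated change, and 3 to 8 unchanged genes were called. Pairs of arrays of a group correlated with r of 0.971 to 0.9967, and 0 pairs were identical.

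The choices below were made before the data were examined. Genes named in the text were, per comparison, a fixed set (Ly6a, Cd34, Kit, Itgae, Gata1, Gata2, Klf1, Epor, Spi1 and Hbb-b1), the 5 largest positive and 5 largest negative called differences with groups that do not overlap and a name that is not a clone or predicted name, and up to 4 called members of each of the 5 lists with the smallest p, or else the member with the largest difference. For the difference of the Epo responses 4 genes each way were named. Some genes that the rule names are not reported here. The 23 lists covered gate markers, globins and red cell membrane, heme synthesis and iron uptake, erythroid transcription factors, stem and multipotent progenitors, granulocytes and monocytes, lymphoid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, macrophages, stroma and endothelium, S phase and mitosis, cell cycle inhibitors, Myc and ribosome biogenesis, autophagy and organelle removal, Epo and Jak-Stat feedback targets, cytokine receptors, interferon response, immediate early and heat shock genes, the BCL2 family, MHC class II presentation, glycolysis, and integrins and homing receptors. Each list was tested with camera at an inter-gene correlation of 0.01 and adjusted over all 138 pairs of list and comparison, and 62 pairs passed. With an estimated correlation 6 passed: mast cell genes in every comparison except CR Sca1lo against Sca1hi and Ediff against EryCP repeat, cytokine receptors in CR Sca1lo against Sca1hi, and interferon response in CD34- CD103- Epo against CD34- CD103-.

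The position of a fraction was the mean, over genes called and at least 2-fold between CD34- CD103- and CD34+ CD103-, of the sign of that difference times the array's level, centred on the mean of the first set, and was compared with an exact 2-sided permutation test whose smallest p is 0.1 with 3 against 3 arrays.

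Alternatives fixed in advance were quantile normalization, normexp background correction (offset 50, on the median signal, since a mean signal is not in the columns used here) before the 75th percentile, no filter on dim probes or one on every array, marked spots kept, eBayes with trend and robust, each probe on its own or the mean over probes, each array left out, all 26 arrays in 1 fit, only the groups compared, slide as a block, a threshold of 0.01, a 2-fold limit, the deposited value table, other gene sets for the position, and camera with an estimated correlation. Chosen after seeing the data were normexp without spots whose local background was marked as outlying, scaling on the 9 spike-in probes well above background on every array, and leaving out slide 2 of the first set, whose arrays had 91.3% to 93.8% of probes well above background, against 80.2% to 87% on slides 1 and 3.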

Results

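Gene expression was measured in EML cells, a mouse haematopoietic line that depends on stem cell factor and can yield erythroid, myeloid and lymphoid progeny. Total RNA of 8 cell populations was hybridised to 26 arrays, each with 1 colour. The first set of 9 arrays held 3 fractions sorted on surface markers, named Sca1hi, CR Sca1lo and EryCP, with 3 arrays each. The second set of 6 arrays held 3 arrays of Ediff, the cells negative for CD34 and cKit that were collected after EryCP cells differentiated under erythropoietin (Epo), and 3 arrays of EryCP cells measured again (EryCP repeat). The third set of 11 arrays held CD34- CD103- and CD34+ CD103- cells, with 4 arrays each, and 3 arrays of CD34- CD103- cells after Epo-driven differentiation (CD34- CD103- Epo). CD103 is the integrin chain encoded by Itgae, and Sca1 is encoded by Ly6a. The 75th percentile of the processed signal lay between 648.8 and 1034 in the first set, between 425.3 and 704.2 in the second and between 757.9 and 1247 in the third. Of the probes on an array 76% to 93.8% were well above background. The labels do not say that samples of a group came from separate cultures. P-values thus measure only the spread between these few samples, which may be technical. Differences are given as log2 values ± standard error with limma's 2-sided adjusted p. Where a gene was not well above background on any array of a group, the fold is a lower bound ("at least"), taken against the dimmest signal that was well above background on each array, or the probe's own signal if higher. In the first set each of the 3 slides held 1 array of each fraction, so that fitting slide as a block left each log2 difference and list median as it was and moved only the p-values.

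CR Sca1lo cells were compared with Sca1hi cells to find what separates neighbouring fractions of the line. Ly6a, the gene of the sorting marker, fell by 5.56 ± 0.14 (n = 3 arrays per fraction, adjusted p = 3.37e-06), or 47.3-fold. Ly6c2, of the same family, was 18.3-fold lower (-4.19 ± 0.17, adjusted p = 4.44e-05). Interferon-induced genes fell with it, led by Rsad2, which encodes the antiviral protein viperin (-2.34 ± 0.22, adjusted p = 0.000975), and Oasl2 (-2.33 ± 0.24, adjusted p = 0.00166). The beta chains of the IL-3, IL-5 and GM-CSF receptors were also lower in CR Sca1lo cells, Csf2rb2 by 3.1-fold (-1.63 ± 0.15, adjusted p = 0.00106) and Csf2rb by 2.84-fold (-1.51 ± 0.2, adjusted p = 0.00592). On the other side, Plac8 was 19.8-fold higher (4.31 ± 0.27, adjusted p = 0.000193). The Myc family gene Mycn was 12.7-fold higher (3.66 ± 0.22, adjusted p = 0.000159) and the growth factor gene Fgf3 8.89-fold higher (3.15 ± 0.27, adjusted p = 0.000653). The macrophage lectin gene Clec10a was 20.7-fold lower (-4.37 ± 0.28, adjusted p = 0.000217), Wfdc17 18.7-fold lower and Pira2, a paired immunoglobulin-like receptor gene, at least 9.4-fold lower. The differences within the 3 slides ran from -5.67 to -5.42 for Ly6a, from 4.06 to 4.66 for Plac8 and from 3.46 to 3.86 for Mycn. Among the genes fixed in advance, these did not pass the test here: Cd34 differed by -0.43 (adjusted p = 0.639), Kit by -0.55 (0.237), Gata1 by -0.28 (0.76), Epor by -0.22 (0.859), Itgae by 0.39 (0.363), Gata2 by 0.43 (0.354) and Spi1 by -0.47 (0.105). Of these Kit (adjusted p = 0.0298, -0.73 to -0.37 within slides), Gata2 (0.01, 0.38 to 0.53) and Spi1 (0.00555, -0.57 to -0.41) were called when slide was fitted as a block. Kit (0.0182) and Spi1 (0.0112) were also called in the fit of all 26 arrays, and Gata2 with quantile normalization (0.0295) and in the deposited value table (0.00655).

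In all, 948 of 26191 genes were called between CR Sca1lo and Sca1hi, 318 higher and 630 lower, of which 178 and 403 differed at least 2-fold. Of the 23 lists 10 passed the test, and the 3 with the smallest p are given here. Of 11 measured interferon response genes 4 were lower and 0 higher, with 8 lower and 1 higher when adjusted over the list alone. The list median was -1.15 (adjusted p = 4.15e-09, or 0.118 with an estimated correlation) and lay between -1.38 and -0.85 within slides, or at -0.62 with normexp. Of 15 cytokine receptor genes 5 were lower and 1 higher (8 and 1 adjusted over the list alone). Their median was -0.46 (adjusted p = 6.06e-09, or 0.0154 with an estimated correlation), or -0.69 to -0.52 within slides. Genes of ribosome biogenesis and Myc shifted the other way as a list, by a median of 0.46 (adjusted p = 4.6e-06, or 0.404 with an estimated correlation). Of its 17 genes 0 passed the test singly, also adjusted over the list alone, and the median lay between 0.36 and 0.53 within slides. Dkc1, which encodes dyskerin, was the member named by rule (0.66, adjusted p = 0.0992, 0.57 to 0.78 within slides), and it was called with slide as a block (0.00434), all 26 arrays in the fit (0.00145), the deposited value table (0.0131), quantile normalization (0.0402) and eBayes with trend and robust (0.046). With slide as a block these lists had adjusted p-values of 5.11e-06, 1.51e-06 and 3.19e-07. The groups of all 948 genes did not overlap, against 18.6% of all genes tested and 10% by chance. That 99.8% of the 948 kept their sign on every slide follows from this lack of overlap and adds no support. When slide was fitted as a block 4665 genes were called, all 948 among them, and 54.2% were higher against 33.5%. The count was 171 with scaling on the spike-in probes (median shift of all genes 0.13), 401 without slide 2, whose arrays had the most probes above background, and 2 with normexp (Ly6a and Ly6c2). It was 460, 370, 412, 411 and 598 when Sca1hi arrays 1 and 2 and CR Sca1lo arrays 1, 2 and 3 were left out in turn.

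EryCP cells were next compared with CR Sca1lo cells. Cd34, a marker of haematopoietic progenitors used in the sorting, fell by 4.72 ± 0.25 (26.3-fold, adjusted p = 4.07e-05). Among erythroid transcription factor genes Klf1 rose by 20.8-fold (4.38 ± 0.25, adjusted p = 5.66e-05), Gata1 by 14-fold (3.81 ± 0.19, adjusted p = 3.31e-05) and Gata2 by 5.02-fold (2.33 ± 0.18, adjusted p = 0.000202). Epor, the receptor gene for erythropoietin, was 6.57-fold higher (2.71 ± 0.17, adjusted p = 8.5e-05) and Itgae 12.6-fold higher (3.66 ± 0.17). The steepest rises were in mast cell and basophil genes: the proteases Mcpt2 (666-fold, 9.38 ± 0.24, adjusted p = 1.13e-06), Mcpt4 (252-fold, 7.97 ± 0.42), Cma2 (171-fold) and Cma1 (146-fold). Hdc, the enzyme that makes histamine, rose 215-fold (7.75 ± 0.19) and Mcpt8 18.4-fold. Red cell genes rose beside them, among them the blood group antigen gene Kel (40.8-fold, 5.35 ± 0.4, adjusted p = 0.000168) and the embryonic globin gene Hbb-bh1 (12.7-fold, 3.66 ± 0.17, adjusted p = 2.58e-05). Alas2, the first enzyme of heme synthesis in red cells, rose as well (6.75-fold, 2.75 ± 0.33, adjusted p = 0.00203). The immediate early genes Fos (5.86-fold), Egr1 (4.22-fold) and Ier3 (4.35-fold) and the cell cycle inhibitor gene Rb1 (3.2-fold) also rose. Genes that fell included the transporter Slco3a1 (9.35-fold, -3.23 ± 0.19), the cytokine gene Il15 (9.19-fold), the Ly49 family gene Klra7 (11.3-fold) and Abca4 (14.3-fold, above background on 2 of 3 EryCP arrays). Within slides Cd34 differed by -4.99 to -4.27, Klf1 by 4.27 to 4.5, Gata1 by 3.54 to 4.21 and Hdc by 7.65 to 7.91.

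The test called 1303 of 26191 genes between EryCP and CR Sca1lo, 714 higher and 589 lower (463 and 342 at least 2-fold). Of the 23 lists 11 passed the test, and the 5 with the smallest p are given first. Of 14 mast cell, basophil and eosinophil genes 10 rose and 1 fell, with the same counts adjusted over the list alone. Their median was 2.26 (adjusted p = 2.22e-18; adjusted p = 0.005 with an estimated correlation), or 2.01 to 2.3 within slides. Of 23 globin and red cell membrane genes 10 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.56 and mean 1.34 (adjusted p = 8.67e-12; adjusted p = 0.137 with an estimated correlation). Of 18 genes of heme synthesis and iron uptake 7 rose and 0 fell (10 and 1 adjusted over the list alone). Their median was 0.62 (adjusted p = 5.66e-08; adjusted p = 0.118 with an estimated correlation). Immediate early and heat shock genes rose in 6 of 13 cases (7 adjusted over the list alone). Their median was 0.7 (adjusted p = 2.23e-08; adjusted p = 0.0556 with an estimated correlation). Cell cycle inhibitor genes rose in 3 of 12 cases (5 adjusted over the list alone). Their median was 0.39 (adjusted p = 7.03e-07; adjusted p = 0.118 with an estimated correlation). With normexp the globin median was 0.02 and that of cell cycle inhibitors 0.65. Within slides these 4 medians ran from 0.55 to 0.58, 0.55 to 0.71, 0.69 to 0.88 and 0.41 to 0.45, and with slide as a block the 5 lists had adjusted p-values of 1.13e-10, 1.46e-06, 8.01e-07, 1.46e-06 and 4.96e-06. Of 15 erythroid transcription factor genes, a list with a larger p, 4 rose and 1 fell (5 and 1 adjusted over the list alone). Their median was 0.31 (adjusted p = 0.00123; adjusted p = 0.118 with an estimated correlation; adjusted p = 0.00444 with slide as a block), or 0.22 to 0.34 within slides, 0.03 with normexp, 0.17 with normexp without spots of outlying background, 0.1 without CR Sca1lo array 2 and 0.08 and 0.5 without EryCP arrays 2 and 3. All 1303 genes had groups that did not overlap, against 18.2% of the genes tested and 10% by chance, from which it follows that 99.8% kept their sign on every slide. The count was 5328 with slide as a block, 436 with spike-in scaling, 75 with normexp (78.7% higher against 54.8%, with the median of all genes at -0.54), and 831 without slide 2. It was 741, 725, 757 and 813 when CR Sca1lo arrays 1 and 2 and EryCP arrays 1 and 3 were left out in turn.

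Across the whole sort, EryCP cells differed from Sca1hi cells in both markers, Ly6a by -6.4 ± 0.14 (84.6-fold, adjusted p = 1.08e-06) and Cd34 by -5.15 ± 0.25 (35.5-fold, adjusted p = 1.92e-05). Hdc was 204-fold higher in EryCP (7.67 ± 0.19, adjusted p = 1.66e-06), Csrp3, a muscle LIM protein gene, 124-fold higher (6.96 ± 0.41), Mcpt2 110-fold, Mcpt4 71.2-fold, Mcpt8 42.8-fold and the high-affinity IgE receptor chain Ms4a2 14.3-fold higher. The neutrophil protein gene S100a8 was at least 49.6-fold higher (7.06 ± 0.59, adjusted p = 0.000229). The erythroid genes Kel (47.1-fold), Hbb-bh1 (27.2-fold, 4.77 ± 0.17, adjusted p = 5.63e-06), Alas2 (7.76-fold) and the transferrin receptor gene Tfr2 (4.57-fold) rose. So did Klf1 (24.1-fold, 4.59 ± 0.25), Itgae (16.5-fold), Gata1 (11.5-fold), Gata2 (6.74-fold), Epor (5.63-fold) and Gfi1b (3.78-fold). Klf3, a relative of Klf1, fell by 1.71 ± 0.16 (adjusted p = 0.000439). Kit, the stem cell factor receptor gene, differed by 0.01 (adjusted p = 1). The interferon-induced genes Rsad2 (25.2-fold, -4.66 ± 0.22, adjusted p = 1.66e-05) and Oasl2 (9.58-fold, above background on 1 of 3 EryCP arrays) and the chemokine gene Ccl5 (31.1-fold) were lower. Within slides Ly6a differed by -6.62 to -6.21, Cd34 by -5.37 to -4.76 and Hdc by 7.3 to 8.13.

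Between EryCP and Sca1hi 1679 genes were called, 814 higher and 865 lower (463 and 528 at least 2-fold). Of the 23 lists 9 passed the test, and the 5 with the smallest p are given here. Of 14 mast cell genes 10 rose and 0 fell (10 and 1 adjusted over the list alone). Their median was 2.44 (adjusted p = 4.33e-16; adjusted p = 0.00507 with an estimated correlation). Of 23 globin and membrane genes 12 rose and 0 fell, also adjusted over the list alone. Their median was 1.45 (adjusted p = 2.08e-12; adjusted p = 0.133 with an estimated correlation), but 0.02 with normexp and 0.81 with normexp without spots of outlying background. Of 11 interferon response genes 7 fell and 1 rose, also adjusted over the list alone. Their median was -1.48 (adjusted p = 1.42e-07; adjusted p = 0.118 with an estimated correlation). Genes of heme synthesis and iron uptake rose in 7 of 18 cases (11 higher and 1 lower adjusted over the list alone). Their median was 0.61 (adjusted p = 7.6e-08; adjusted p = 0.118 with an estimated correlation). Of 15 erythroid transcription factor genes 6 rose and 1 fell, also adjusted over the list alone. Their median was 0.31 (adjusted p = 0.000225; adjusted p = 0.118 with an estimated correlation). Within slides the medians ran from 2.09 to 2.62 for mast cell genes, 1.16 to 1.72 for globins, -1.7 to -1.18 for interferon genes, 0.55 to 0.74 for heme genes and 0.26 to 0.43 for transcription factors. The slide-blocked adjusted p-values were 1.33e-08, 6.7e-07, 6.19e-05, 8.71e-07 and 0.000628. All 1679 genes had groups that did not overlap, against 18.9% of those tested and 10% by chance, from which it follows that 99.8% kept their sign on every slide. The count was 5477 with slide as a block, 611 with spike-in scaling, 97 with normexp (median of all genes -0.5), and 1113 without slide 2. It was 998, 829, 964 and 1029 when Sca1hi arrays 1 and 2 and EryCP arrays 1 and 3 were left out in turn.

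**Figure D1:**
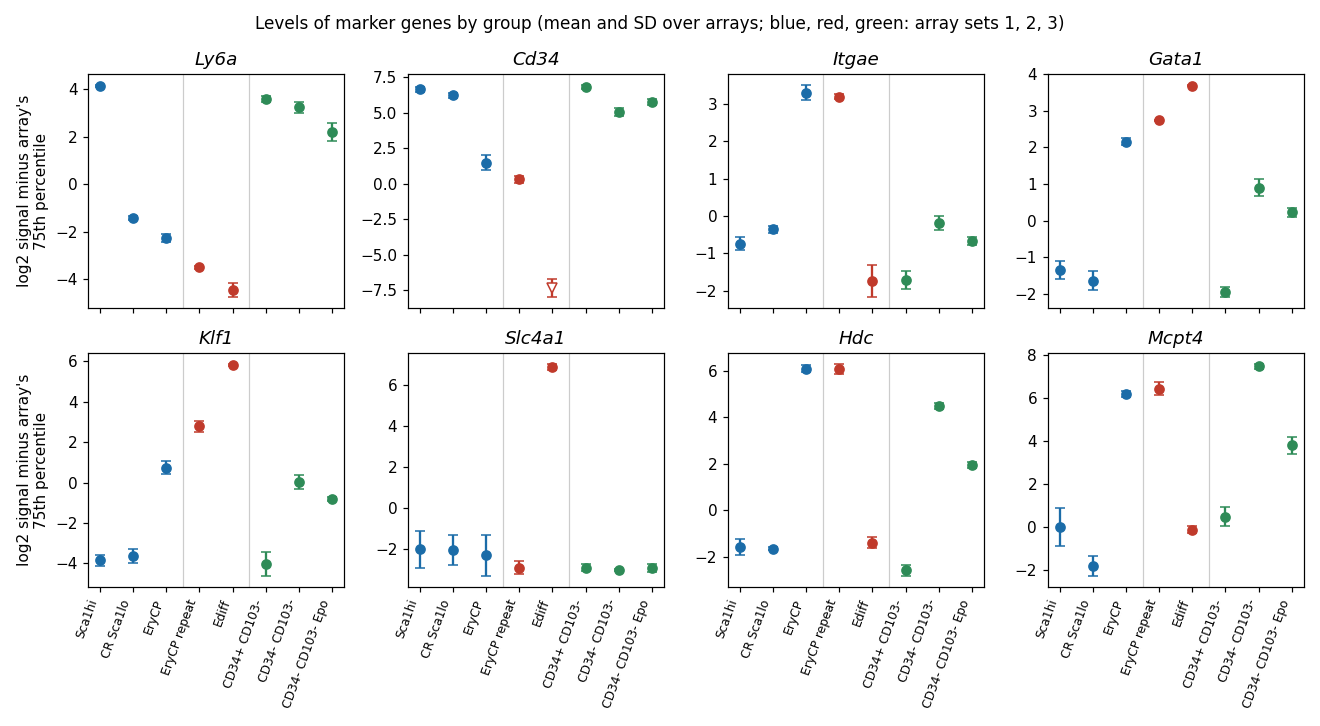
Log2 levels of 8 genes relative to each array's 75th percentile, as mean ± SD of the arrays of each group, with an open triangle where no array of a group was well above background. Ly6a dropped from 4.15 in Sca1hi to -1.41 in CR Sca1lo, Cd34 from 6.22 in CR Sca1lo to 1.5 in EryCP, and Slc4a1 reached 6.87 in Ediff. Levels of different array sets were not tested against each other.

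Ediff cells were compared with EryCP cells on the same slides to follow erythroid differentiation under Epo. Among the steepest rises were the embryonic alpha-like globin gene Hba-x, 1660-fold (standard error 0.28 on the log2 scale, adjusted p = 3.3e-06) and the red cell anion exchanger gene Slc4a1, 856-fold (9.74 ± 0.19, adjusted p = 1.51e-06). The ankyrin gene Ank1 rose 198-fold, the Rhesus antigen gene Rhd 195-fold and Alas2 142-fold (7.15 ± 0.1, adjusted p = 1.22e-06). Tmod1 was at least 145-fold higher, Cyp4b1 at least 221-fold higher and Tent5c 481-fold higher, although Tent5c was above background on 1 of 3 EryCP repeat arrays. The iron importer gene of mitochondria, Slc25a37, rose 17.9-fold (4.16 ± 0.11, adjusted p = 3.32e-06), the heme enzyme genes Cpox 12.4-fold and Alad 11.7-fold, Epor 8.74-fold (3.13 ± 0.13) and Klf1 8.23-fold (3.04 ± 0.16, adjusted p = 3.41e-05). Ediff cells were collected as negative for CD34 and cKit, and Cd34 was at least 78-fold lower (-7.64 ± 0.34, adjusted p = 1.77e-05) and Kit 9.91-fold lower (-3.31 ± 0.12, adjusted p = 8.04e-06), which the collection itself selected for. Gata2 fell 11.2-fold (-3.48 ± 0.17) and Itgae 30.4-fold. Mast cell genes fell as well, Mcpt8 1190-fold (-10.22 ± 0.29, adjusted p = 3.8e-06, above background on 2 of 3 Ediff arrays) and the carboxypeptidase gene Cpa3 433-fold (-8.76 ± 0.2, adjusted p = 2.02e-06). Hdc fell 177-fold, the granzyme gene Gzmb 132-fold and Hpgds, a prostaglandin D synthase gene, at least 91.8-fold. The chemokine receptor gene Ccr2 was at least 203-fold lower, and among adhesion genes Itga6 fell 20.6-fold, Icam2 12.3-fold and Pecam1 10.4-fold. Gata1 was 1.94-fold higher (0.95 ± 0.08, adjusted p = 0.000225), but at -0.11 with spike-in scaling, and Ly6a was lower by -0.96 (adjusted p = 0.00472), but at 0.25 with normexp. Within the 2 slides Hba-x differed by 10.17 to 10.96, Slc4a1 by 9.41 to 9.87, Alas2 by 7.1 to 7.18, Kit by -3.44 to -3.09 and Mcpt8 by -10.54 to -9.68. These were 10.57, 9.64, 7.14, -3.27 and -10.11 when slide was fitted as a block. The 31 genes named by rule moved by at most 0.3 with slide as a block, and each kept its sign and call.

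The test called 13855 of 24463 genes, 56.6%, between Ediff and EryCP repeat, 9732 higher (70.2%) and 4123 lower, with 2887 and 2191 at least 2-fold, and the median of all genes was 0.46. All 24 globin and red cell membrane genes rose, also adjusted over the list alone. Their median was 4.76 (adjusted p = 1.49e-11; adjusted p = 0.201 with an estimated correlation). All 18 genes of heme synthesis and iron uptake rose, also adjusted over the list alone. Their median was 2.45 (adjusted p = 5.66e-08; adjusted p = 0.157 with an estimated correlation). Of 15 erythroid transcription factor genes 13 rose and 0 fell, also adjusted over the list alone. Their median was 1.06, but -0.01 with spike-in scaling (adjusted p = 0.000564; adjusted p = 0.153 with an estimated correlation). Of 9 Epo and Jak-Stat feedback targets 8 rose and 0 fell, also adjusted over the list alone. Their median was 3.17 (adjusted p = 0.000643; adjusted p = 0.17 with an estimated correlation). Of 14 mast cell genes 11 fell and 1 rose (11 and 2 adjusted over the list alone). Their median was -4.07 (adjusted p = 3.31e-09; adjusted p = 0.118 with an estimated correlation). All 4 gate markers, among them Cd34 and Kit on which Ediff cells were collected, were lower, also adjusted over the list alone (median -4.12, adjusted p = 0.000132; adjusted p = 0.118 with an estimated correlation). With slide as a block the medians of these 6 lists were 4.78, 2.5, 1.06, 3.27, -4.31 and -4.17. Within slides they ran from 4.62 to 4.93, 2.46 to 2.52, 0.98 to 1.37, 3.04 to 3.49, -4.66 to -3.97 and -4.23 to -4.1. The median of Epo and Jak-Stat targets was 1.36 with normexp, 2 with normexp without spots of outlying background, 2.1 with spike-in scaling and 2.08 in the deposited value table. Normexp also brought those of erythroid transcription factors, mast cell genes and gate markers to 0.66, -2.35 and -2.43, and spike-in scaling that of heme genes to 1.39. Groups did not overlap for 98% of the called genes and 63.3% of all tested, against 10% by chance. The 99.9% of the calls that kept their sign on both slides largely follow from this lack of overlap. The share of higher genes followed the scaling. It was 59% of 12722 with quantile normalization (median of all genes 0.19), 58.2% of 12548 in the deposited value table and 24% of 242 with normexp. It was 80.2% of 19913 with normexp without spots of outlying background, and 6.57% of 12555 with scaling on the spike-in probes, where the median of all genes was -0.61.

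In the third set CD34- CD103- cells were compared with CD34+ CD103- cells. Cd34 itself was 3.44-fold lower (-1.78 ± 0.16, n = 4 arrays per fraction, adjusted p = 3.12e-05) and Itgae 2.89-fold higher (1.53 ± 0.13, adjusted p = 2.26e-05). Mast cell genes were furthest apart, Hdc 134-fold higher (7.07 ± 0.13, adjusted p = 8.6e-10), Mcpt4 127-fold (6.99 ± 0.22), Cma2 121-fold (6.92 ± 0.28) and Mcpt2 98.7-fold. Cma1 rose 26.8-fold and the tryptase gene Tpsb2 18.4-fold. Blood group and membrane genes rose with them, Ermap at least 55.3-fold, Kel 43.8-fold (5.45 ± 0.14, adjusted p = 4.58e-09) and Rhd at least 5.11-fold. Klf1 rose 16.5-fold (4.04 ± 0.27, adjusted p = 3.97e-06), Gata1 7.25-fold (2.86 ± 0.13, adjusted p = 1.71e-07), Epor 4.63-fold and Gata2 3.45-fold. The heme and iron genes Blvrb (4.34-fold), Alas2 (1.22 ± 0.14, adjusted p = 0.000238), Alad (1.06, adjusted p = 0.000557) and Slc11a2 (0.96, adjusted p = 1.19e-05) rose by smaller amounts. Fos (3.49-fold, 1.8 ± 0.33, adjusted p = 0.00459) and Egr1 (3.3-fold) were also higher. The myeloid transcription factor gene Spi1 fell by 0.54 ± 0.11 (adjusted p = 0.0106). The genes that fell most were Tnfrsf1a (4.27-fold), which encodes a TNF receptor, and Slco3a1 (4.25-fold). Next came the granulocyte receptor gene Csf3r (4.2-fold, above background on 1 of 4 CD34- CD103- arrays), the neutrophil granule gene Pglyrp1 (4.19-fold, -2.07 ± 0.1, adjusted p = 5.01e-07) and Abca4 (4.12-fold). Ly6a differed by -0.35 (adjusted p = 0.247, but -0.65 and 0.0101 with spike-in scaling) and Kit by 0.33 (adjusted p = 0.0917, but 0.0259 without CD34- CD103- array 1 and 0.0478 with trend and robust). Within the 3 slides Hdc differed by 7.02 to 7.15, Kel by 5.32 to 5.68, Klf1 by 3.92 to 4.59, Gata1 by 2.7 to 3.09 and Cd34 by -2.17 to -1.55. The slide-blocked differences were 7.09, 5.53, 4.22, 2.91 and -1.84. The 36 genes named by rule moved by at most 0.18 with slide as a block, and 35 kept their call.

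Between CD34- CD103- and CD34+ CD103- cells 3394 of 27075 genes were called, 1540 higher and 1854 lower (394 and 190 at least 2-fold). Of 24 globin and membrane genes 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 1.22 (adjusted p = 2.16e-16; adjusted p = 0.0639 with an estimated correlation). Of 14 mast cell genes 10 rose and 1 fell, also adjusted over the list alone. Their median was 1.64 (adjusted p = 4.33e-16; adjusted p = 0.005 with an estimated correlation). Of 18 heme and iron genes 9 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.38 (adjusted p = 2e-07; adjusted p = 0.118 with an estimated correlation). Immediate early and heat shock genes rose in 6 of 13 cases (9 adjusted over the list alone). Their median was 0.81 (adjusted p = 1.04e-05; adjusted p = 0.146 with an estimated correlation). Of 17 genes of ribosome biogenesis and Myc 5 fell and 0 rose (10 and 0 adjusted over the list alone). Their median was -0.27 (adjusted p = 0.00052; adjusted p = 0.118 with an estimated correlation). Of 15 erythroid transcription factor genes 8 rose and 2 fell, also adjusted over the list alone. Their median was 0.29, but -0.02 with spike-in scaling (adjusted p = 0.000785; adjusted p = 0.393 with an estimated correlation). Blocking on slide gave medians of 1.24, 1.7, 0.41, 0.74, -0.24 and 0.27, and within slides they ran from 0.9 to 1.89, 1.53 to 1.91, 0.35 to 0.55, 0.28 to 0.94, -0.24 to -0.23 and 0.15 to 0.38. Of 16 megakaryocyte and platelet genes 7 rose and 1 fell (7 and 2 adjusted over the list alone). Their median was 0.18, but -0.13 with spike-in scaling (adjusted p = 0.000643, or 0.133 with an estimated correlation), or 0.26 for slide as a block and 0.23 to 0.41 within slides. Of 12 cell cycle inhibitor genes 4 rose and 1 fell (6 and 1 adjusted over the list alone). Their median was 0.24, but -0.06 with spike-in scaling (adjusted p = 0.00501, or 0.118 with an estimated correlation), or 0.22 for slide as a block and 0.08 to 0.39 within slides. The heme median was 0.07 and the Myc median -0.58 with spike-in scaling, and the Myc median -0.17 with quantile normalization. Normexp gave 0.65 for globins and 0.18 for transcription factors, and the median of immediate early genes was 0.44 with normexp, 0.5 with normexp without spots of outlying background and 0.5 with spike-in scaling. Groups did not overlap for 95.5% of the called genes and 17.2% of all tested, against 2.86% by chance, and 99.5% of the calls kept their sign on all 3 slides. Scaling on the spike-in probes called 9542 genes, 5.94% of them higher against 45.4%, with the median of all genes at -0.37.

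CD34- CD103- cells after Epo-driven differentiation were compared with CD34- CD103- cells. The largest falls included S100a8 by 50.7-fold (-5.66 ± 0.53, adjusted p = 0.000174) and S100a9 by 44.5-fold (-5.48 ± 0.44, adjusted p = 5.25e-05), whose products form calprotectin. Lcn2, a neutrophil gene whose product binds siderophores, was at least 9.41-fold lower and the lysozyme gene Lyz2 5.53-fold lower (-2.47 ± 0.09, adjusted p = 3.09e-07). Among mast cell genes, Tpsb2 fell by 17.6-fold (-4.14 ± 0.19, adjusted p = 1.14e-06), Mcpt4 by 12.7-fold (-3.67 ± 0.24), Hdc by 5.85-fold (-2.55 ± 0.14, adjusted p = 2.73e-06) and Cma1 by 3.39-fold. Wfdc17 was 37.6-fold lower and Mrgprb1, a mast cell receptor gene, 47.9-fold lower, above background on 1 and 2 of the 3 Epo arrays, and P2ry10b at least 12.9-fold lower. The blood group genes Kel (2.91-fold, -1.54 ± 0.15, adjusted p = 0.000257) and Ermap (5.06-fold, -2.34 ± 0.23, adjusted p = 0.000233) fell too. Rises were small, the largest being Serpinf1 (1.04 ± 0.12, adjusted p = 0.000767, but 0.0563 with spike-in scaling) and Slco3a1 (1.01 ± 0.13, adjusted p = 0.00296). Klf1 differed by -0.82 (adjusted p = 0.197), Epor by -0.52 (0.196), Cd34 by 0.7 (0.0642), Kit by -0.35 (0.184) and Spi1 by 0.22 (0.404), which was -0.03 with spike-in scaling. Epor reached -0.75 (adjusted p = 0.00405) with slide as a block and -0.57 (0.0443) with normexp without spots of outlying background, where Cd34 was at 0.73 (0.0453; 0.0293 with trend and robust). Ly6a was lower by -1.03 (adjusted p = 0.0126), but -0.89 (adjusted p = 0.0506) with slide as a block. Gata1 differed by -0.68 (adjusted p = 0.0274; -0.82 and 0.0117 with slide as a block), a call lost without CD34- CD103- array 3 (0.0771) and without Epo arrays 1, 2 or 3 (0.0511, 0.129 and 0.134). Within slides 6 and 7, the only ones of the set with Epo arrays, S100a8 differed by -6.46 to -4.14, Tpsb2 by -4.37 to -4.08, Hdc by -2.72 to -2.4 and Lyz2 by -2.56 to -2.34. Fitted with slide as a block, these were -5.41, -4.3, -2.54 and -2.48. The 33 genes named by rule moved by at most 0.49 with slide as a block, and 29 kept their call.

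For CD34- CD103- Epo against CD34- CD103- the test called 704 of 27075 genes, 186 higher and 518 lower, with 4 and 180 at least 2-fold. Of 14 mast cell genes 7 fell and 0 rose, also adjusted over the list alone. Their median was -0.57 and mean -1.07 (adjusted p = 1.59e-11; adjusted p = 0.00507 with an estimated correlation). Of 11 interferon response genes 2 fell and 0 rose (4 and 0 adjusted over the list alone). Their median was -0.43 (adjusted p = 2.06e-05; adjusted p = 0.0285 with an estimated correlation), but -0.09 with normexp, -0.12 with normexp without spots of outlying background and -0.68 with spike-in scaling. Of 24 globin and membrane genes 5 fell and 0 rose (7 and 0 adjusted over the list alone). Their median was -0.11 and mean -0.52 (adjusted p = 7.06e-06; adjusted p = 0.159 with an estimated correlation). Of 21 granulocyte and monocyte genes 6 fell and 2 rose (7 and 2 adjusted over the list alone). Their median was -0.08 and mean -0.89 (adjusted p = 0.000236; adjusted p = 0.153 with an estimated correlation), and the median turned to 0.14 with normexp and to 0.12 with normexp without spots of outlying background. Genes of ribosome biogenesis and Myc rose in 2 of 17 cases (5 adjusted over the list alone). Their median was 0.25 (adjusted p = 9.12e-06; adjusted p = 0.115 with an estimated correlation), with a median of 0 under spike-in scaling and 0.15 with quantile normalization and in the deposited value table. Spike-in scaling gave -0.36 for globins and -0.33 for granulocyte and monocyte genes, and the mast cell median was -0.87 with normexp without spots of outlying background. Heme and iron genes had a median of -0.02 (1 of 18 higher, 0 lower, adjusted p = 0.534) and erythroid transcription factors of 0 (0 of 15 higher, 1 lower, adjusted p = 0.45). Epo and Jak-Stat targets had a median of 0.23 (0 of 9 higher, 1 lower, adjusted p = 0.925), or -0.01 with spike-in scaling. With slide as a block the medians of the 5 shifted lists with the smallest p were -0.51, -0.45, -0.27, -0.08 and 0.23. Within slides the interferon median was -0.27 on both, and the medians ran from -0.5 to -0.17 for mast cell genes, from -0.57 to -0.37 for globins, from -0.32 to 0.22 for granulocyte genes and from 0.22 to 0.3 for Myc genes. All 704 genes had groups that did not overlap, against 19.2% of those tested and 5.71% by chance, and 98.7% kept their sign on both slides. The count was 335 without Epo array 3, 375 without Epo array 2, 390 without Epo array 1, 440, 449 and 463 without CD34- CD103- arrays 4, 2 and 3, and 365 with normexp. The share of higher genes was 26.4%, against 45.6% of 750 with normexp without spots of outlying background and 1.22% of 574 with spike-in scaling (median of all genes -0.17).

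A further 6 lists passed in this comparison. Cytokine receptor genes fell in 2 of 15 cases (6 lower and 1 higher adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00112; adjusted p = 0.118 with an estimated correlation). Cell cycle inhibitor genes passed singly in 0 of 12 cases (2 lower adjusted over the list alone), with a median of -0.16 (adjusted p = 0.00251; adjusted p = 0.118 with an estimated correlation). S phase and mitosis genes rose in 1 of 23 cases (4 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00375; adjusted p = 0.409 with an estimated correlation). Immediate early and heat shock genes fell in 2 of 13 cases (3 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0135; adjusted p = 0.436 with an estimated correlation). Glycolysis genes passed singly in 0 of 15 cases (3 higher adjusted over the list alone), with a median of 0.19 (adjusted p = 0.0273; adjusted p = 0.212 with an estimated correlation). Of 4 gate markers 1 was lower (3 lower and 1 higher adjusted over the list alone), with a median of -0.42 (adjusted p = 0.0325; adjusted p = 0.135 with an estimated correlation). In this order the medians were -0.15, -0.09, 0.11, -0.03, 0.13 and -0.44 with slide as a block, where the calls of immediate early genes (adjusted p = 0.171) and gate markers (0.152) were lost. Within slides they ran from -0.28 to -0.13, -0.16 to -0.15, 0.09 to 0.11, -0.03 to 0.01, 0.07 to 0.16 and -0.47 to -0.31. The S phase call was lost with quantile normalization (0.08), normexp (0.15), normexp without spots of outlying background (0.14), the deposited value table (0.09) and spike-in scaling (-0.09). So was that of glycolysis (0, 0.13, 0.15, 0.01 and -0.06). Spike-in scaling gave -0.43, -0.41, -0.4 and -0.67 for cytokine receptors, cell cycle inhibitors, immediate early genes and gate markers, of which the last lost its call, and normexp with and without those spots gave -0.02 and -0.01 for immediate early genes. Calls were also lost for S phase genes without Epo array 1 (adjusted p = 0.0835), for glycolysis without CD34- CD103- array 1 (0.0775) or Epo array 2 (0.0649), for immediate early genes without CD34- CD103- array 2 (-0.09, 0.143) or Epo array 3 (0.0654), and for gate markers without CD34- CD103- arrays 2 (0.0531) or 3 (0.0649).

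**Figure D2:**
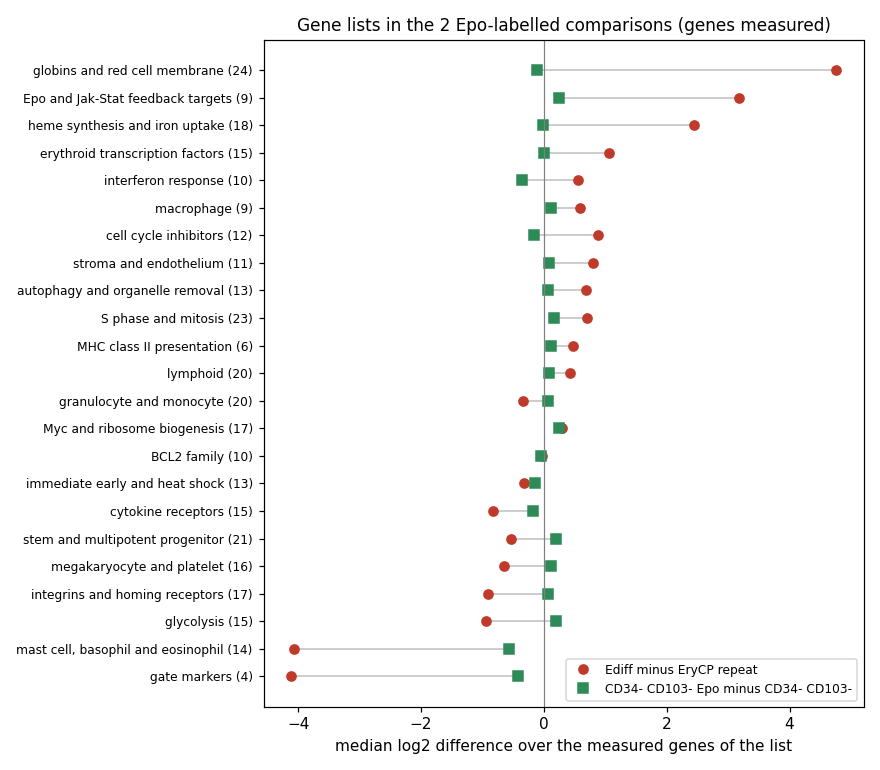
Median log2 difference of each of the 23 gene lists in Ediff minus EryCP repeat (red circles) and in CD34- CD103- Epo minus CD34- CD103- (green squares), over the genes kept across the 13 arrays of both sets together. Some medians therefore differ from those within a set, such as granulocyte and monocyte genes at -0.34 and 0.07, a list whose direction turned with normexp in both comparisons. Globins and red cell membrane genes stood at 4.76 and -0.11, heme genes at 2.45 and -0.02 and mast cell genes at -4.07 and -0.57. Erythroid transcription factors stood at 1.06 and 0, with the first at -0.01 when arrays were scaled on the spike-in probes.

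The Epo responses of both sets were then compared in 1 test of the difference over 13 arrays. Erythroid genes responded more in Ediff: Hba-x by 10.61 ± 0.37 (adjusted p = 1.76e-09), with a response of 0.09 in CD34- CD103- Epo, Slc4a1 by 9.65 ± 0.21 (9.74 in Ediff and 0.09 in CD34- CD103- Epo, adjusted p = 9.33e-11), and Rhd by 11.15 ± 0.52 (7.6 and -3.54). Mast cell genes fell further in Ediff, Mcpt8 by -9.19 ± 0.34 (-10.22 and -1.03, adjusted p = 2.62e-09) and Cpa3 by -8.61 ± 0.21 (-8.76 and -0.15, adjusted p = 1.29e-10). Cyp4b1 differed by 9.91 ± 0.46, Ccr2 by -9.02 ± 0.22 and Cd34 by -8.34 ± 0.4. These 3 and Rhd rest on a group that was not well above background, so that their sizes are those of fitted values. Cd34 was selected against when Ediff cells were collected, and that gate may bear on the other genes. The 8 genes moved by at most 0.36 with slide as a block and kept their calls. The test called 10233 of 27007 genes, 6375 with a higher and 3858 with a lower response in Ediff (62.3% higher). The share was 49.6% of 8892 with quantile normalization, 54.5% of 8711 in the deposited value table, 29.1% of 793 with normexp and 10.4% of 8482 with spike-in scaling, where the median of all genes moved from 0.37 to -0.45.

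To place the fractions of the first sets along the difference between CD34- CD103- and CD34+ CD103- cells, each array was scored over 580 of the 584 genes that were called and at least 2-fold in that comparison, 392 higher and 188 lower, those measured on every array of the first and second sets. Higher scores lie on the CD34- CD103- side. EryCP lay at 1.147 ± 0.039 (SD, n = 3), Sca1hi at -0.397 ± 0.132 and CR Sca1lo at -0.75 ± 0.162, so that EryCP stood 1.897 above CR Sca1lo and 1.544 above Sca1hi, and CR Sca1lo -0.353 from Sca1hi. Ediff lay at 0.762 ± 0.026 and EryCP repeat at 1.213 ± 0.062, a difference of -0.451. In each pair the groups did not overlap, and each exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Within slides EryCP stood 1.77 to 2.123 above CR Sca1lo and 1.366 to 1.708 above Sca1hi, CR Sca1lo -0.416 to -0.238 from Sca1hi, and Ediff -0.495 and -0.407 from EryCP repeat. With every called gene in the score, whatever its fold, the place of Ediff turned to 0.072 above EryCP repeat. In a comparison added after the data were examined, across 16456 genes, which are not independent replicates, the EryCP minus CR Sca1lo and the CD34- CD103- minus CD34+ CD103- differences, measured on different arrays, had a Pearson's r of 0.787 and a Spearman's rho of 0.605. Of the 872 genes called in both 868 had the same sign, 492 higher in both against 37.7 by chance and 376 lower in both against 36.

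**Figure D3:**
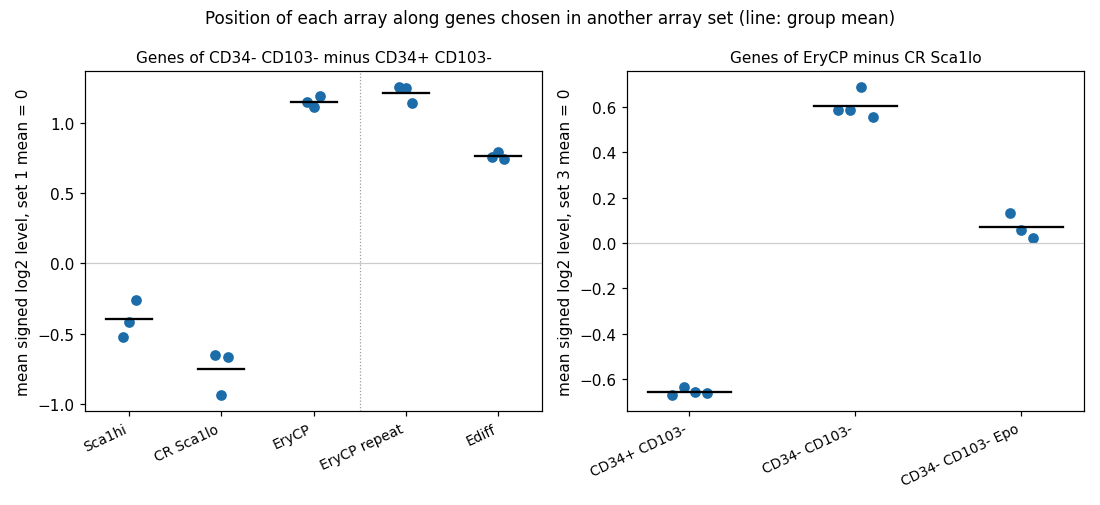
Scores of single arrays. On the left the arrays of the first and second sets are scored over the genes that separate CD34- CD103- from CD34+ CD103- cells, with EryCP at a mean of 1.147 and CR Sca1lo at -0.75. On the right the arrays of the third set are scored over the genes that separate EryCP from CR Sca1lo cells, with CD34- CD103- at 0.604, CD34- CD103- Epo at 0.07 and CD34+ CD103- at -0.656.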

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

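The tests of mixtures, exchanged arrays, scaling and array positions and the counts over splits that keep the slides were chosen only after the results they bear on were seen, while the summed signal, the counts over all other splits of the arrays and the difference of the Epo responses were planned.

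Among the named genes, 8 of 108 tested groups of 4 arrays held 1 array apart from the other 3, against 5.4 by chance, with a gap to the nearest array that took up most of the group's range. In CD34- CD103- cells array 3 was apart for 4 genes. Its level was 3.04 for Blvrb against 3.13 to 3.14 (gap over range 0.913), 4.59 for Cd34 against 5.17 to 5.25 (0.882), -4.12 for Kctd14 against -3.83 to -3.81 (0.939) and 2.76 for S100a8 against 2.43 to 2.46 (0.904). Array 1 of the same group was apart for Kit, at 4.28 against 4.63 to 4.65 (0.953). In CD34+ CD103- cells array 2 was apart for Cma2, at -0.97 against -1.37 to -1.33 (0.906). Array 1 was apart for Ermap, at -6.95 against -6.47 to -6.41 (0.896), and for P2ry10b, at -6.08 against -9.04 to -8.67 (0.873).

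The Epo response differed between Ediff and CD34- CD103- Epo for 10233 genes by limma's test of the difference. It was larger in Ediff for Rhd (11.15), Hba-x (10.61), Cyp4b1 (9.91) and Slc4a1 (9.65), and lower for Mcpt8 (-9.19), Ccr2 (-9.02), Cpa3 (-8.61) and Cd34 (-8.34), against which Ediff cells were selected. Of 100 splits of the 13 arrays 5 gave as many genes, the real one included, and the highest other gave 15355, so that chance was not excluded by this count. That highest count came from the 8 drawn splits that kept Ediff apart from EryCP repeat, which gave 9015 to 15355 genes, 4 of them as many as the real split, whereas the highest among the others was 1348. The count therefore follows a structure of the arrays, the division of Ediff from EryCP repeat. The 2 responses also come from different array sets, so that set, cell population and the gate on Ediff cells cannot be told apart in their difference.

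Of the 518 genes lower in CD34- CD103- Epo than in CD34- CD103- cells, 74 (14.3%) were also lower than in CD34+ CD103- cells, among them Wfdc17 (-4.13 against CD34+ CD103-), Lyz2 (-0.97) and, chosen after their values were seen, Gfi1 (-2.56) and Mmp8 (-1.4). Both comparisons share the Epo arrays, and in 20 simulations unchanged groups gave 0 genes lower than CD34- CD103- and 0 lower than both, a mixture with 75% of CD34+ CD103- signal gave 968 and 1.5, and independent lists would give 15.2, so that part of the excess may come from the shared arrays. A mixture lies between its parts, so the 14.3% argues against CD34+ CD103- cells in the Epo samples as the whole cause, and 62.5% of the 24 genes at least 8-fold higher in CD34- CD103- cells, whose falls ran from -0.96 to -5.01, lay over 3 standard errors from the common fall of -2.05, which argues against 1 share of such cells in every sample. The falls of 4 mast cell genes above their CD34+ CD103- level ran from -1.13 for Ms4a2 to -3.78 for Mcpt4, a range of 9.32 standard errors of their difference, which argues against a smaller share of 1 mast cell population, and 0 Epo arrays lay within the range of the CD34- CD103- arrays along the EryCP minus CR Sca1lo genes, which argues against exchanged arrays. A change of expression within the cells under Epo and several populations that lost unequal shares stay open and were not tested.

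Genes called between Ediff and EryCP repeat were mostly higher (70.2% of 13855), but 6.57% of 12555 were higher with the arrays scaled on the spike-in probes, which moved the median of all genes from 0.46 to -0.61. The direction of the split thus depended on the scaling, and these values do not show which scaling is right. Over the spike-in signal the 75th percentile stood at -3.23 ± 0.06 (SD, n = 3) in Ediff and -2.28 ± 0.14 in EryCP repeat, while the summed signal fell from 14.95 to 14.48, a difference of -0.47 or 49.7% of the change of the percentile. This lies between the bounds set before the result was seen, so that a few genes taking most of the signal stays open, with 49.1% of it in the brightest 1% of spots in Ediff against 41.2% in EryCP repeat. Less messenger RNA in the total RNA of differentiated cells, or unequal amounts of spike-in RNA, may give the same values, and neither was tested.

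Scored over 776 of the 805 genes called and at least 2-fold between EryCP and CR Sca1lo in the first set, those measured on every array of both the first set and that of the CD34- CD103- cells, 446 higher and 330 lower, CD34- CD103- arrays lay at 0.604 ± 0.058 (SD, n = 4), CD34- CD103- Epo arrays at 0.07 ± 0.054 (n = 3) and CD34+ CD103- arrays at -0.656 ± 0.015 (n = 4). The differences were 1.26 for CD34- CD103- minus CD34+ CD103-, -0.533 for Epo minus CD34- CD103- and 0.727 for Epo minus CD34+ CD103-, each with an exact 2-sided permutation p = 0.0286, the smallest possible and 0.0286 adjusted over the 3. These permutations take no account of slide, and over the 18, 6 and 9 splits that keep the slides p was 0.0556, 0.167 and 0.111, the smallest that they allow. On slides 6, 7 and 8 the first was 1.257, 1.338 and 1.226, and on slides 6 and 7 the others were -0.509 and -0.631, and 0.748 and 0.707. Such a position is a mean over the differences of single genes, of which 868 of the 872 called in both EryCP minus CR Sca1lo and CD34- CD103- minus CD34+ CD103- had the same sign, so it describes these differences and is no independent test of where the cells lie.

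For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and 1 of 10 gave as many genes in each. The real and the highest other counts were 948 and 1 for CR Sca1lo against Sca1hi, 1303 and 0 for EryCP against CR Sca1lo, 1679 and 0 for EryCP against Sca1hi, and 13855 and 0 for Ediff against EryCP repeat. Of the 35 splits of the CD34- CD103- and CD34+ CD103- arrays 1 gave as many as 3394 genes, the real one, and the highest other gave 14. Of the 35 splits of the Epo and CD34- CD103- arrays 1 gave as many as 704, and the highest other gave 0. Chance was excluded for both over these splits, which take no account of slide. The splits that keep the number of arrays of each group on every slide were 18 and 6, too few for a share under 0.05, and among them the highest other count was 0 for both, against 3394 and 704.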

How the results depend on the processing

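The alternatives chosen after seeing the data are those named above, and the others were fixed before. Of 2679 recomputed values of the 203 named gene results, 2487 kept direction and side of the threshold, 151 lost the call, 32 gained one, 6 moved and 3 changed direction, and of 1377 with 1 array left out 1294, 80, 1, 2 and 0 did. For the 138 list results these were 1080, 88, 15, 54 and 5 of 1242, and 806, 25, 15, 51 and 0 of 897. There direction is that of the test, not of the median. Slide as a block kept 191 of the named gene results, with 4 calls lost and 8 gained, and 125 of the list results, with 7 calls lost. The lists lost were globins (adjusted p = 0.146), immediate early genes (0.0648) and stem cell genes (0.0648) in CR Sca1lo against Sca1hi, stem cell genes (0.0793) in EryCP against CR Sca1lo, Epo and Jak-Stat targets (0.0739) in EryCP against Sca1hi, and gate markers (0.152) and immediate early genes (0.171) in the Epo comparison of the third set. Every call of a probe near background is limited by signal over background, since 76% to 93.8% of the probes of an array were well above it. Scan date as a block was not run, because each set was scanned on 1 day. No paired analysis was possible, since no 2 groups compared share a sample number in the labels. Slide was fitted as a block in its place.

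Counts that moved by over 1.5 times are given for CR Sca1lo against Sca1hi (948 as reported), EryCP against CR Sca1lo (1303) and EryCP against Sca1hi (1679), in this order. They were 401, 693 and 854 at an adjusted p under 0.01, and 581, 805 and 991 with a 2-fold limit, both stricter by construction. With fewer arrays in the fit they were 562, 756 and 1026 for only the groups compared and 401, 831 and 1113 without slide 2, and with all 26 arrays they were 3053, 3494 and 3670. They were 4665, 5328 and 5477 with slide as a block, 171, 436 and 611 with spike-in scaling, 2226, 3000 and 2912 in the deposited value table and, for the first pair, 1619 and 2314 with quantile normalization, and the cause was not tested. Normexp gave 2, 75 and 97, then 242 for Ediff against EryCP repeat (13855 as reported), 365 for Epo against CD34- CD103- (704) and 793 for the difference of the Epo responses (10233). Without spots of outlying background these 6 were 1030, 1534, 1779, 19913, 750 and 10769, so the counts rose when such spots were left out. The highest local background was 137950 on Sca1hi array 3 and 152991 on CR Sca1lo array 2, where the 10th percentile after normexp was 1259 and 1281, against 65.39 and 76.19 on Sca1hi array 2 and CR Sca1lo array 1, and it was 72255.5 on Ediff array 1 (percentile 1122) and 68222.5 and 70728 on EryCP repeat arrays 1 and 3, where it was 824 and 139.4, so the highest background alone did not set it. No Epo or CD34- CD103- array had one above 98, but CD34+ CD103- array 3, in the same fit, had 10592. Ediff against EryCP repeat gave 8542 genes at 0.01 and 5078 with a 2-fold limit, CD34- CD103- against CD34+ CD103- (3394) gave 1842, 584 and, with spike-in scaling, 9542, and Epo against CD34- CD103- gave 326 and 184, 446 with all 26 arrays and 1092 with trend and robust. The difference of the Epo responses gave 5018 with a 2-fold limit. Of the 62 list calls 6 held with an estimated correlation.

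With 1 array left out the counts ran from 370 to 637, 725 to 1030, 829 to 1327, 9594 to 16931, 2510 to 3599, 335 to 761 and 8442 to 12765 in the order of the comparisons, and the list calls from 56 to 65. Positions ran from -0.415 to -0.259 for CR Sca1lo minus Sca1hi, 1.482 to 1.613 for EryCP minus Sca1hi, 1.804 to 1.947 for EryCP minus CR Sca1lo and -0.564 to -0.404 for Ediff minus EryCP repeat.

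Jun in EryCP against CR Sca1lo turned from 1.16 to -0.18 and Ly6a in Ediff from -0.96 to 0.25 with normexp, and Gata1 in Ediff from 0.95 to -0.11 with spike-in scaling. Medians of S phase and mitosis genes turned from -0.01 to 0.3 (EryCP against CR Sca1lo) and from -0.04 to 0.24 (EryCP against Sca1hi) and that of Myc genes in EryCP against CR Sca1lo from -0.41 to 0.04 with normexp. Glycolysis in the Epo comparison of the third set went from 0.19 to 0 with quantile normalization and to 0.01 in the deposited value table, where the direction of its test turned. The position of EryCP over CR Sca1lo (1.897) was 2.067 with quantile normalization, 1.777 with normexp, 3.02 over genes at least 4-fold apart at an adjusted p under 0.01 and 0.823 over every called gene. For EryCP over Sca1hi (1.544) normexp gave 1.409 and these gene sets 2.592 and 0.64, and for CR Sca1lo minus Sca1hi (-0.353) every called gene gave -0.183. For Ediff minus EryCP repeat (-0.451) the values were -0.562 with quantile normalization, -0.591 with normexp without spots of outlying background, -1.192 over the stricter set and 0.072 over every called gene. Apart from the gene sets, which change the score by construction, the cause was not tested.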

Other observations

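The list tests in this part were planned, while the single genes and the comparison of both Epo differences across genes were chosen only after the values were seen. As Ediff cells arose from EryCP cells, glycolysis genes fell in 11 of 15 cases and rose in 4, also adjusted over the list alone. Their median was -0.95 (limma and camera, adjusted p = 0.000188; adjusted p = 0.397 with an estimated correlation), or -0.91 with slide as a block and -1.03 to -0.89 within slides. Hk2, a hexokinase gene, fell by 3.58 ± 0.12 (n = 3 arrays per group, adjusted p = 6.3e-06; -3.58 with slide as a block, -3.75 to -3.41 within slides), and the pyruvate kinase gene Pkm by 3.53 ± 0.17 (adjusted p = 2.13e-05; -3.51 and -3.7 to -3.32). The glucose transporter gene Slc2a1 rose by 1.3 ± 0.1 (adjusted p = 0.000176; 1.33 and 1.32 to 1.34), or by 0.24 with spike-in scaling. Integrins and homing receptors fell in 11 of 17 cases and rose in 4, also adjusted over the list alone, with a median of -0.91 (adjusted p = 5.24e-05, or 0.118 with an estimated correlation), or -0.89 with slide as a block and -0.91 to -0.83 within slides. Cd47 rose by 1.63 ± 0.09 (adjusted p = 3.23e-05; 1.62 and 1.59 to 1.64), or by 0.57 with spike-in scaling. The Epo signalling target Cish rose by 4.44 ± 0.11 (adjusted p = 2.75e-06; 4.47 and 4.34 to 4.61). The glycolysis median was -1.52 with quantile normalization and -2.01 with spike-in scaling, and the integrin median -1.98 with spike-in scaling.

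Markers of other lineages moved in Ediff as well. Of 18 granulocyte and monocyte genes 10 fell and 3 rose, also adjusted over the list alone. Their median was -1.39, or -0.44 with dim genes at their bound and 0.22 with normexp (adjusted p = 0.000785; adjusted p = 0.259 with an estimated correlation; adjusted p = 0.0659 with spike-in scaling), with -1.34 for slide as a block and -1.48 to -1.2 within slides. The granule protease gene Ctsg fell by 7.76 ± 0.13 (adjusted p = 1.32e-06; -7.82 with slide as a block, -7.86 to -7.77 within slides). Of 19 stem and multipotent progenitor genes 9 fell and 5 rose (9 and 6 adjusted over the list alone), with a median of -0.31, but 0.04 with normexp (adjusted p = 0.00375; adjusted p = 0.118 with an estimated correlation; -0.18 with slide as a block, -0.32 to -0.28 within slides). Of 16 megakaryocyte and platelet genes 8 fell and 4 rose (10 and 4 adjusted over the list alone), with a median of -0.65 (adjusted p = 0.00455; adjusted p = 0.118 with an estimated correlation; adjusted p = 0.155 with spike-in scaling), or -0.65 with slide as a block and -0.76 to -0.64 within slides. S phase and mitosis genes rose in 18 of 23 cases and fell in 1, also adjusted over the list alone, with a median of 0.7 but -0.36 with spike-in scaling (adjusted p = 0.00771; adjusted p = 0.713 with an estimated correlation; adjusted p = 0.241, 0.057 and 0.146 with normexp, normexp without spots of outlying background and spike-in scaling). This median was 0.73 with slide as a block and 0.68 to 0.83 within slides. Cytokine receptor genes fell in 9 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone), with a median of -0.83 (adjusted p = 0.000236; adjusted p = 0.133 with an estimated correlation; adjusted p = 0.0508 with spike-in scaling), or -0.77 with slide as a block and -0.87 to -0.77 within slides. The granulocyte median was -0.11 with normexp without spots of outlying background and -0.52 in the deposited value table, the megakaryocyte median -0.41 with normexp, the S phase median 0.46 with quantile normalization and 0.34 with normexp, and the cytokine receptor median -0.18 and -0.35 with normexp with and without those spots. Spike-in scaling gave -2.45, -1.37, -1.71 and -1.9 for granulocyte, stem cell, megakaryocyte and cytokine receptor genes.

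Vwf, the gene of von Willebrand factor, did not follow the order of the sort. It was lower in CR Sca1lo than in Sca1hi cells by -3.61 ± 0.23 (n = 3, adjusted p = 0.000218; -3.84 to -3.32 within slides) and higher in EryCP than in CR Sca1lo cells by 3.34 ± 0.23 (adjusted p = 0.000131; 2.91 to 3.92). In CD34- CD103- against CD34+ CD103- cells it was 2.99 ± 0.16 higher (n = 4, adjusted p = 8.4e-07; 3.07 with slide as a block, 2.93 to 3.14 within slides). Meis1, a transcription factor gene of stem cells, was lower in EryCP than in CR Sca1lo cells by -3.12 ± 0.14 (adjusted p = 2.28e-05; -3.31 to -3.02) and in CD34- CD103- than in CD34+ CD103- cells by -1.75 ± 0.2 (adjusted p = 0.000227; -1.84 with slide as a block, -2.31 to -1.58 within slides).

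A further 10 lists did not pass the test between Ediff and EryCP repeat, and their medians were all negative with spike-in scaling. Lymphoid genes had a median of 0.42, a mean of -0.27 and a test toward lower values (5 of 18 higher, 7 lower, adjusted p = 0.122), autophagy and organelle removal a median of 0.68 (9 of 13 higher, 1 lower, adjusted p = 0.191) and macrophage genes of 0.53 (4 of 8 higher, 1 lower, adjusted p = 0.665). Stroma and endothelium genes had a median of 0.82 (6 of 10 higher, 1 lower, adjusted p = 0.665), and MHC class II presentation of 0.6 with a mean of 0.02 and a test toward lower values (2 of 6 higher, 1 lower, adjusted p = 0.883). Adjusted over the list alone these counts were the same except for stroma genes (7 higher, 2 lower). The BCL2 family stood at -0.03 (4 of 10 higher, 4 lower, also adjusted over the list alone, adjusted p = 0.427). Blocking on slide gave medians of 0.15, 0.71, 0.39, 0.69, 0.49 and -0.07, and within slides they ran from -0.04 to 0.25, 0.68 to 0.74, 0.28 to 0.59, 0.55 to 0.65, 0.34 to 0.51 and -0.1 to 0.01. Immediate early and heat shock genes had a median of -0.33 (4 of 13 higher, 6 lower, or 5 and 6 adjusted over the list alone, adjusted p = 0.121), a list that passed with normexp (adjusted p = 0.00329). Myc and ribosome genes stood at 0.29 (8 of 17 higher, 0 lower, also adjusted over the list alone, adjusted p = 0.32) and cell cycle inhibitors at 0.88 (6 of 12 higher, 3 lower, or 7 and 3 adjusted over the list alone, adjusted p = 0.478). Interferon response genes had a median of 0.55 and a mean of 0.86, with a test toward lower values (4 of 9 higher, 3 lower, also adjusted over the list alone, adjusted p = 0.98). The medians of these 4 with slide as a block were -0.38, 0.39, 0.76 and 0.36, and within slides they ran from -0.37 to -0.36, 0.31 to 0.45, 0.79 to 0.85 and 0.37 to 0.56.

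Across 15756 genes, which are not independent replicates, the Ediff minus EryCP repeat and the Epo minus CD34- CD103- differences, measured on different arrays, had a Pearson's r of 0.167 and a Spearman's rho of 0.151. Of 403 genes called in both 249 had the same sign, 61.8%. Lower in both were 202 against 66.3 by chance, higher in both 47 against 58.6, higher in Ediff and lower in Epo 92 against 145.8, and lower in Ediff and higher in Epo 62 against 26.6. These counts depend on the scaling, while r was 0.147 to 0.204 under the scalings tried. With spike-in scaling 265 of 313 (84.7%) had the same sign, 264 of them lower in both against 186.2 by chance, and 44 were higher in Ediff and lower in Epo against 13.4. The share was 86.7% of 30 with normexp and 59.5% to 64.1% with the other scalings.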
